A study of Mus musculus with 14 samples.

How the data were processed

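The samples are 14 droplet-based single-cell RNA libraries of sorted cells from mouse spleen. The labels describe splenic monocytes at 1 week or 4 weeks after immunization and give each library a B6, BALB or C3H label. The titles name the cells as coming from B6, BALB or C3H mice. The groups hold 2 libraries per label at week 1, and 3 B6, 3 BALB and 2 C3H libraries at week 4. The descriptions of the samples name other tissues, lymph node at week 1 and tumor at week 4, which the titles contradict, and the conflict could not be settled from the files. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between libraries, which could be technical. The B6, BALB and C3H labels are used as labels only, since the check of strain-related genes did not tell the labels apart.

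For each library the authors deposited a matrix of unique molecular identifier (UMI) counts per gene and barcode, as whole numbers without normalization. The counts were made with Cell Ranger and the mm10 genome, per the submitters' processing notes, and the matrices were written by version 3.0.2, per the file headers. The deposited matrices hold 29605 barcodes and 31053 genes, and the 14 libraries hold between 1558196 and 21153813 counts each. The gene identifiers and symbols came from the files. Coordinates came from GENCODE release M21, which uses GRCm38 (mm10), and 30934 of the 31053 identifiers matched it. The 71 genes whose symbol is shared by another identifier were kept apart by their identifiers.

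Barcodes with at least 500 detected genes and at most 10% mitochondrial counts were kept, which left 19041. The Scrublet doublet caller in scanpy 1.11.5, run per library at its default threshold, removed 172 barcodes (0.903%), and 18869 cells remained. The caller removed 1 barcode in each of B6 week 1 replicate 1 and C3H week 1 replicate 2, the libraries with the most kept cells at week 1. It removed 56 (10.2%) in BALB week 1 replicate 2 and 41 (2.30%) in B6 week 1 replicate 2, so doublets were removed unevenly. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components with 15 neighbours were clustered by the Leiden method at resolution 1. No batch integration was used, and 16 clusters resulted.

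Clusters were named from marker sets fixed before the data were examined. A class name needed 3 markers at 50 CPM (counts scaled by the library total) or more and a median log2 fold over the remaining cells of at least 1, with 10 CPM added. A cluster with Csf1r and at least 5 classical monocyte markers at 50 CPM counted as monocyte-like, and as classical monocyte-like from a median log2 fold of 0.25. These thresholds of the naming rule were set after the clusters had been seen. All 16 clusters had at least 6 classical markers at 50 CPM, the basophil or mast cell-like cluster included. That condition therefore does not separate monocytes from other cells. The plain name monocyte-like rests on Csf1r and on no class passing its own rule. Clusters whose median mitochondrial share was 5% or more stayed unnamed as low quality, and this threshold also replaced an earlier rule after the clusters had been seen. A monocyte name also needed at least as many of its own markers as of any other class among the 10 leading genes of the cluster. That last condition was applied after gene counts under a wider class had been seen. It left clusters 3 and 6 unnamed, and the counts with both added back are given as an alternative. Monocyte-like cells were those of clusters 2, 4, 5, 8, 9 and 10, 10067 in all, of which cluster 8 was nonclassical monocyte-like.

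Gene differences were tested on the counts summed per library over monocyte-like cells, with the quasi-likelihood test of edgeR 4.0.16, TMM normalization, filterByExpr and a group means model of all 14 libraries. P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. The standard errors (SE) of log2 fold changes come from the fold change and its F statistic. The fit tested 7594 genes with 8 residual degrees of freedom and a biological coefficient of variation of 0.112. The smallest sum of a library was 325438 counts. The comparisons were BALB against B6, C3H against B6 and C3H against BALB averaged over the weeks, week 4 against week 1 averaged over the labels, BALB and C3H against B6 within each week, and the interactions of both with week.

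The fixed lists of genes covered paired Ig-like receptors, other myeloid receptors, MHC class I and class II presentation, type I interferon response, interferon-gamma-induced genes, NF-kB and inflammatory cytokines, immediate early and dissociation stress, glycolysis, oxidative phosphorylation, cholesterol, costimulation, phagocytosis and complement, migration, chromatin-modifying enzymes, cell cycle, classical and nonclassical monocyte genes, cytosolic ribosomal proteins and mitochondrially encoded genes. Lists for other cell types covered neutrophils, B cells, T and NK cells, dendritic cells, red pulp macrophages, red cells and platelets, and basophils, mast cells and eosinophils. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Lists tested within a week were added to the comparisons averaged over weeks after the data had been seen.

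Shares of cells were compared with exact two-sided permutation tests of the mean logit share, with 0.5 added to each count, adjusted over 8 tests. Labels were exchanged within week for comparisons of labels, and within label for the week comparison.

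Named genes followed a rule fixed before the data were examined. For comparisons averaged over weeks or labels it took up to 10 genes per direction past the threshold, with a mean log2 CPM of at least 3 and every library of one group above every library of the other within each week or label. For comparisons within a week and interactions it took up to 5 per direction. For each list it took up to 4 members with the smallest p. Genes of the label check, the paired Ig-like receptors, H2-K1, H2-D1, B2m, Ly6c2, Ccr2, Nr4a1 and Cx3cr1 were always included. Genes named outside this rule, among them those that lead a cluster, were chosen after their values were seen.

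The tests were checked on simulated counts with 200 changed genes per comparison. The changed genes were drawn from those above a minimum mean level. All simulated libraries had the same mean profile, without the cluster and library differences of the real data. With BALB against B6 averaged over weeks, 91% of 2-fold changes and 100% of 4-fold changes among 7307 genes were recovered, and with week 4 against week 1 93% and 100% among 7306 genes. With BALB against B6 the recovery was 88% and 100% at week 1 among 7329 genes, and 53% and 94% at week 4 among 7314 genes. With C3H against B6 it was 80% and 100% averaged over weeks among 7307 genes, 89% and 100% at week 1 among 7301 genes, and 48% and 89% at week 4 among 7328 genes. The BALB interaction recovered 36% of 2-fold and 87.9% of 4-fold changes among 7329 genes. False calls made up 3.55% (BALB against B6 averaged over weeks) to 7.73% (C3H against B6 averaged over weeks) of the calls.

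The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a log2 fold change of at least 1, cells with at least 200 or at least 1000 genes, doublets kept, Leiden resolutions 0.5 and 2, all kept cells, classical-like or nonclassical-like cells alone, a replicate block, the compared groups alone, sums thinned to the smallest library, sex-linked and lymphocyte receptor genes left out, and each library left out in turn. Sums without nonclassical-like cells, with low-quality clusters added, and with both unnamed clusters of monocyte genes added were tried after the data had been seen, as were shares with the unnamed and low-quality clusters added together. Libraries of a group were compared for duplicates, and the chi-square per degree of freedom between them lay between 1.40 and 13.4, so none was counted as a copy. Intervals and floors cover counting error only.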

Results

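The data are UMI counts from 14 single-cell libraries of sorted mouse splenic cells, taken 1 week or 4 weeks after immunization and labelled B6, BALB or C3H. The series title names paired immunoglobulin-like receptors (PIR) and innate memory to non-self MHC molecules, so the comparisons ask how monocyte transcripts differ between the labels and between the weeks. Each label has 2 libraries at week 1, and B6, BALB and C3H have 3, 3 and 2 libraries at week 4. Total counts per library ran from 2253154 to 21153813 at week 1 and from 1558196 to 4850705 at week 4. The median count per barcode lay between 4690 and 6501 in 5 of the 6 week 1 libraries, was 1143 in C3H week 1 replicate 1, and lay between 655 and 1114 in the 8 week 4 libraries. The median mitochondrial share per barcode was 1.41% to 1.89% in those 5 week 1 libraries, 5.53% in C3H week 1 replicate 1 and 5.28% to 8.87% at week 4. Depth per barcode and RNA quality therefore differ together with week. The titles name splenic monocytes, while the free-text descriptions name lymph node for the week 1 libraries and tumor for the week 4 libraries. If the descriptions hold, week also differs together with tissue.

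Genes that check the labels were measured over all kept cells of each library. Il2rg, the common gamma chain of several cytokine receptors, had 43 counts over all 14 libraries and at most 1.67 CPM in any of them, while Il10rb, a chain of the interleukin 10 receptor, lay between 71.3 and 107 CPM. Il10rb was chosen after the values were seen. Rag2 lay between 34.8 and 59.1 CPM and Rag1 had 0 counts. Cd3e, Igkc, Ncr1 and Gzma, genes of T, B and NK cells that were also chosen after the values were seen, had 0 counts each in all libraries, while the B cell gene Cd79a, chosen likewise, had 18 counts and up to 1.65 CPM, and a count of 0 allows 2.55 CPM in the shallowest library. Xist lay between 311 and 1006 CPM in every library, and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 counts. Nnt, whose transcript is low in C57BL/6J mice, lay between 1.48 and 8.75 CPM, and BALB differed from B6 by 0.108 CPM (exact permutation p = 0.917). H2-Ea, which is silent in mice of the C57BL/6 type, is not among the genes of the files. No gene was above 20 CPM in every library of one label and below 1 CPM in every library of another. The titles name B6, BALB and C3H mice, but these genes do not show the labels to be mouse strains. The text therefore writes of libraries labelled B6, BALB and C3H.

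Cells classed as monocyte-like made up most of the kept cells in the mean of each label at week 1 and fewer at week 4. In C3H week 1 replicate 1 they were 46.5%. Monocyte-like cells were 74.6% ± 0.0008 (SD, n = 2) of kept cells in B6, 65.3% ± 3.98 (n = 2) in BALB and 58.7% ± 17.3 (n = 2) in C3H at week 1. At week 4 they were 23.02% ± 1.16 (n = 3), 26.2% ± 6.95 (n = 3) and 30.7% ± 5.80 (n = 2). Low-quality clusters with monocyte genes held 3.38%, 6.02% and 20.3% of kept cells of B6, BALB and C3H at week 1, and 27.3%, 33.2% and 35.5% at week 4. The C3H week 1 value averages 38.6% in replicate 1, the low-quality library, and 2.05% in replicate 2. Clusters 3 and 6, with monocyte genes but led by cycling and haemoglobin genes or by MHC class II genes, held 14.5%, 19.7% and 14.02% at week 1 and 25.3%, 14.9% and 11.1% at week 4. Both kinds were left out of the monocyte-like class. With both added, the class held 92.5%, 91.02% and 93.1% of kept cells of B6, BALB and C3H at week 1 and 75.7%, 74.2% and 77.3% at week 4. Different clusters held the monocyte-like cells of different groups. Cluster 2, led by Mmp8 and Chil3, held 45.5% of them in B6 at week 1 but 3.33% in BALB and 12.9% in C3H at week 1, and 5.49% or less in each label at week 4. The B6 value comes mostly from replicate 1, with 58.6% of its monocyte-like cells in cluster 2 against 13.7% in replicate 2, and C3H replicates 1 and 2 had 1.66% and 14.1%. Cluster 9, led by Tppp3, Hes1 and Nr4a1, held 19.7%, 26.8% and 28.3% of them in B6, BALB and C3H at week 1.

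Nonclassical-like cells were defined by genes such as Fabp4, Eno3, Cd300e and Ace. Averaged over labels, their share of the monocyte-like cells was larger at week 4 than at week 1. How much larger depends on which cells are counted as monocyte-like. At week 1 the nonclassical-like cells were 7.20% ± 2.79 (n = 2) in B6, 25.7% ± 0.283 (n = 2) in BALB and 17.0% ± 4.68 (n = 2) in C3H. At week 4 they were 53.2% ± 6.21 (n = 3), 50.9% ± 10.3 (n = 3) and 53.1% ± 0.0189 (n = 2). Averaged over labels the share was 35.8 percentage points higher at week 4 (exact permutation p = 0.00167, the smallest this design allows, adjusted p = 0.00667), and the monocyte-like share of kept cells was lower, with a difference of -39.6 points (exact permutation p = 0.00167, adjusted p = 0.00667). The share difference was 10.1 to 25.9 points under other gene minimums, Leiden resolutions or with doublets kept, and 19.4 points with clusters 3 and 6 added. With these and the low-quality clusters added it was 6.68 points and no longer past the threshold (exact permutation p = 0.015, adjusted p = 0.06). The difference in the monocyte-like share was then -16.5 points (exact permutation p = 0.00167, adjusted p = 0.0133). In that setting the nonclassical share went from 18.4% to 17.3% in BALB, from 5.78% to 16.2% in B6 and from 10.3% to 21.1% in C3H. The added cells entered the total only, since none of them could count as nonclassical-like. They therefore lower the share most where they are most frequent. Cluster 1, of low quality, had a median log2 fold of 0.997 for nonclassical and 0.552 for classical markers. The smaller difference thus does not show that the share was alike in both weeks. Of all kept cells, nonclassical-like cells went from 16.8% to 12.9% in BALB, from 5.37% to 12.3% in B6 and from 9.59% to 16.3% in C3H. Averaged over weeks, the nonclassical share did not differ detectably between BALB and B6 (8.13 points, exact permutation p = 0.217, adjusted p = 0.433), between C3H and B6 (4.87 points, p = 0.183, adjusted p = 0.433) or between C3H and BALB (-3.26 points, p = 0.433, adjusted p = 0.578). The smallest exact p that each of these label tests allows is 0.0167. Under the 7 other cell definitions the C3H and B6 difference lay between 4.71 and 13.4 points (exact permutation p = 0.0167 to 0.133) and passed the threshold in cells with at least 200 genes (8.71 points, adjusted p = 0.0444, and 0.0889 to 0.178 in the others). The BALB and B6 difference lay between 6.92 and 17.4 points, and that of C3H and BALB between -8.89 and 1.76 points, with 4 of 7 above 0 (1 of 7 on the logit scale of the test). By week, the BALB and B6 difference was 18.5 points at week 1 and -2.24 at week 4, and the change between them was not detectable (-20.7 points, exact permutation p = 0.133). Under the other cell definitions it was 10.9 to 23.5 points at week 1 and turned to 1.17 to 11.9 at week 4, and the interaction lay between -17.8 and -7.93 points. The difference in the monocyte-like share of kept cells was -3.03 points for BALB against B6 (exact permutation p = 0.417, adjusted p = 0.578), -4.10 for C3H against B6 (p = 0.8, adjusted p = 0.914) and -1.08 for C3H against BALB (p = 1, adjusted p = 1). Under the other cell definitions these lay between -7.87 and -1.44, between -11.5 and 1.11 and between -7.81 and 6.31 points, so the last 2 have no settled direction.

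**Figure D1:**
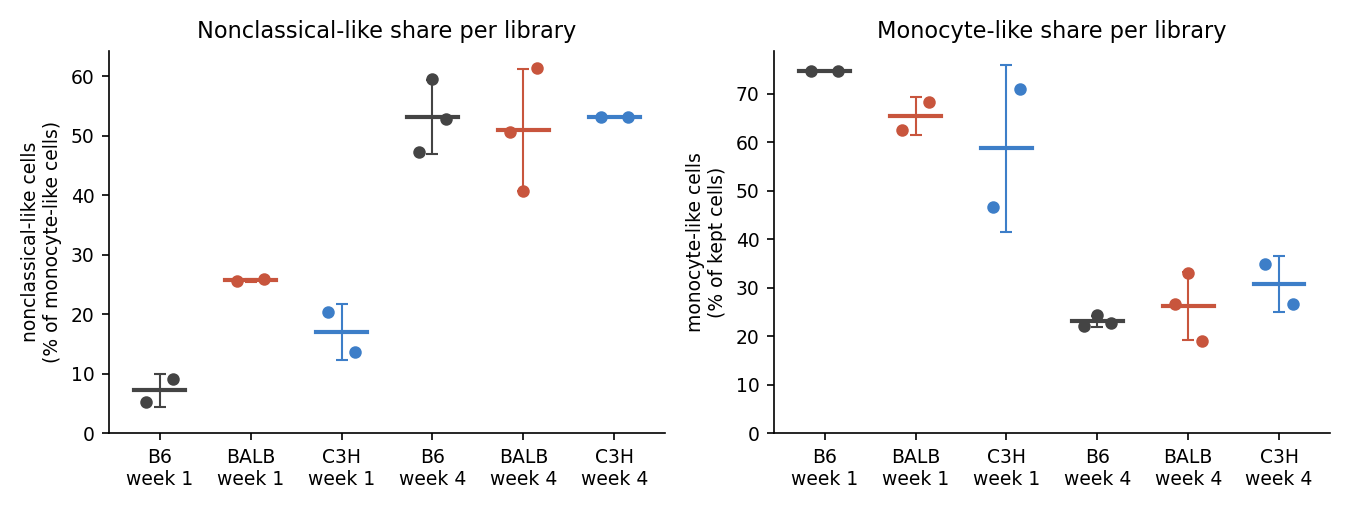
Nonclassical-like cells as a percentage of monocyte-like cells (left) and monocyte-like cells as a percentage of kept cells (right), 1 point per library, with the group mean as a line and the SD as a bar. The nonclassical-like share averaged 7.20% in B6 week 1 and 25.7% in BALB week 1, and the 8 libraries of week 4 lay between 40.8% and 61.4%.

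Monocyte-like cells of the libraries labelled BALB differed from those labelled B6 at week 1 in 303 genes. Of the tested lists, 13 of 20 nonclassical monocyte genes rose, and 45 of 78 ribosomal genes fell while 2 rose, although neither list passed camera with an estimated correlation. Lilra5, an activating Ig-like receptor of myeloid cells, was at 11.3 ± 1.68 CPM (SD, n = 2) in BALB and 1.45 ± 0.053 CPM (n = 2) in B6, a log2 fold change of 2.99 ± 0.34 (SE, edgeR adjusted p = 0.000163). Ace, angiotensin-converting enzyme, rose by 1.74 ± 0.23, from 42.1 ± 10.2 CPM in B6 (edgeR adjusted p = 0.000483). Lpl, lipoprotein lipase, was at 42.1 ± 6.94 CPM in BALB and 103 ± 36.2 CPM in B6, with a log2 fold change of -1.25 ± 0.23 (edgeR adjusted p = 0.00468). Of 7594 genes, 198 rose and 105 fell (edgeR, Benjamini-Hochberg). The Lilra5 gene (ENSMUSG00000070873) lies on chromosome 7 from 4237754 to 4243463, Ace (ENSMUSG00000020681) on chromosome 11 from 105967945 to 105989964, and Lpl (ENSMUSG00000015568) on chromosome 8 from 68880491 to 68907448 (GRCm38).

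Of the 20 genes of the nonclassical list tested at week 1, 13 rose and 0 fell in BALB (15 and 1 adjusted over the list alone), among them Ace, Adgre4 (1.17 ± 0.19), the Notch target Hes1 (1.12 ± 0.17, but -0.071 in classical-like cells alone) and Treml4 (1.10 ± 0.24). Camera gave an adjusted p of 8.93e-18 for the list and 0.144 with an estimated correlation, while fry gave 0.0143. These genes also define cluster 8, whose share differed between these libraries. Of 18 classical monocyte genes, 0 rose and 1 fell, Hp (-0.54 ± 0.14), with 6 that fell adjusted over the list alone (camera adjusted p = 0.00519, and adjusted p = 0.252 with an estimated correlation). Of 78 cytosolic ribosomal protein genes, 45 fell and 2 rose, with Rps12 at -0.85 ± 0.13 and Rps20 at -0.74 ± 0.12 (camera adjusted p = 1.35e-33, and adjusted p = 0.203 with an estimated correlation). Of 12 mitochondrially encoded genes 4 fell, among them mt-Nd1 (-0.63 ± 0.15) and mt-Nd4 (-0.60 ± 0.13), with a camera adjusted p of 2.91e-05 and an adjusted p of 0.273 with an estimated correlation.

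Among genes of antigen presentation, 4 of 23 MHC class I genes rose and 0 fell in BALB at week 1, including H2-Q6 (2.10 ± 0.36) and H2-Q4 (1.51 ± 0.33), members of a family of near-identical copies whose counts are uncertain. Camera gave an adjusted p of 0.00342, and 0.364 with an estimated correlation. H2-K1, H2-D1 and B2m, which form the classical class I molecules, had log2 fold changes of 0.08 ± 0.13, 0.33 ± 0.13 and 0.26 ± 0.12 (edgeR adjusted p = 0.799, 0.176 and 0.229). Of 8 MHC class II genes 1 rose, Cd74 (1.43 ± 0.25), the invariant chain. Cluster 6, led by MHC class II genes, was left out of the cells tested. The log2 fold change of Cd74 lay between 0.41 and 1.68 in 32 alternatives and was past the threshold in 27. Of 53 type I interferon genes 1 rose, Oas1a (1.19 ± 0.29), and the list median was 0.35 (camera adjusted p = 1.09e-05, and adjusted p = 0.513 with an estimated correlation). Pirb, the inhibitory PIR, was lower in BALB at week 1 (255 ± 31.0 CPM against 359 ± 45.9 CPM, log2 fold change -0.50 ± 0.13, edgeR adjusted p = 0.0277). Its log2 fold change lay between -0.64 and -0.37 in 32 alternatives and was past the threshold in 19 of them. The other PIR genes tested, Pira2, Lilra6 and Gm14548, had log2 fold changes of 0.13 ± 0.17, -0.21 ± 0.14 and -0.28 ± 0.19 (edgeR adjusted p = 0.733, 0.447 and 0.458). PIR genes are near-identical copies, so reads shared between them make these values uncertain.

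Further genes that rose in BALB at week 1 were Lpcat4 (2.23 ± 0.45, but -0.090 after thinning to the smallest library), Cfb, complement factor B (2.13 ± 0.36), Spag7 (1.84 ± 0.40), Itgax, the integrin CD11c (2.20 ± 0.37), Sirpb1a (1.42 ± 0.21), Cd300ld (1.11 ± 0.19) and Abcg1, a cholesterol exporter (1.21 ± 0.19). Those that fell included Prtn3, the granule protease proteinase 3 (-1.85 ± 0.33), Cdk5rap1 (-1.67 ± 0.45), Ier3 (-1.47 ± 0.37) and Fam20c (-1.27 ± 0.35). Fam20c was past the threshold in 7 of 28 alternatives and Cdk5rap1 in 16 of 28, and the log2 fold change of both was negative in all 28. DESeq2 called 253 genes in place of 303. Without B6 replicate 1 the edgeR count was 60, without BALB replicate 1 it was 103, without BALB replicate 2 it was 88, without B6 replicate 2 it was 197, and without C3H week 1 replicate 1 or 2 it was 513 or 514.

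Averaged over the weeks, few genes differed between the libraries labelled BALB and B6, and none did by edgeR without nonclassical-like cells or in classical-like cells alone (618 and 474 genes at an unadjusted p under 0.05, DESeq2 not run on these sums). Bcl2a1d, a survival gene with near-identical copies (0.97 ± 0.15), Lilra5 (1.27 ± 0.24), Ace (0.94 ± 0.16), Adgre4 (0.67 ± 0.13) and Pmaip1, which encodes the BH3-only protein Noxa (0.62 ± 0.12), rose, and the ribosomal genes Rps20 (-0.47 ± 0.08), Rps12 (-0.47 ± 0.09) and Rplp1 (-0.42 ± 0.07) fell. All 8 passed the edgeR threshold, with adjusted p between 0.0143 for Bcl2a1d and 0.0493 for Pmaip1 and Adgre4. Rps20 (ENSMUSG00000028234, chromosome 4 from 3831334 to 3835665) met the ranking rule for named genes, Lilra5, Ace, Adgre4 and Rps12 are members of the gene lists, and Bcl2a1d, Pmaip1 and Rplp1 are named after their values were seen. At week 4 these genes had smaller differences, with log2 fold changes of -0.45 ± 0.33 for Lilra5, 0.13 ± 0.21 for Ace and -0.19 ± 0.10 for Rps20.

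By list, 2 of 20 nonclassical genes rose (15 adjusted over the list alone), and 2 of 78 ribosomal genes fell (59 adjusted over the list alone). Camera passed 13 lists in BALB against B6 averaged over weeks, and 0 of them passed with an estimated correlation, where the smallest adjusted p was 0.125. The ribosomal list passed fry, with an adjusted p of 0.0412. Neutrophil genes, of another cell type, had log2 fold changes above 0 in BALB for 6 of 6 tested, and none of them passed the edgeR threshold. Their median was 0.62 (camera adjusted p = 0.00780, and 0.125 with an estimated correlation), and at week 4 it was 0.71 (camera adjusted p = 0.00129, and 0.104 with an estimated correlation). BALB week 4 replicate 3 and B6 week 4 replicate 2 lay apart from the other week 4 libraries in a multidimensional scaling of all genes, at 1.63 and -1.36 and at 0.815 and 1.26 on its axes. The count of 8 genes was 815 at an unadjusted p under 0.05 and 91 with DESeq2, and it was 0 without nonclassical-like cells, 115 without either C3H week 1 library and 0 without BALB week 4 replicate 1 or 3.

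Monocyte-like cells of the libraries labelled C3H showed few detectable gene differences from those labelled B6. At week 1 Lilra5 rose by 2.21 ± 0.36 (edgeR adjusted p = 0.0319), to 7.46 ± 1.5 CPM (SD, n = 2) from 1.45 ± 0.053 CPM (n = 2), and it was the single gene past the threshold. Its log2 fold change lay between 1.30 and 2.53 in 29 alternatives and was past the threshold in 13 of them (edgeR adjusted p up to 0.710), and not past it without B6 week 1 replicate 1 or C3H week 1 replicate 1. Adgre4 had a log2 fold change of 0.86 ± 0.20, Cd74 of 1.07 ± 0.25 and Itgal of 0.84 ± 0.20 at week 1 (edgeR adjusted p = 0.217 each). Averaged over weeks, Chil3, a lectin of classical monocytes, had a log2 fold change of -0.72 ± 0.14 (edgeR adjusted p = 0.0941) and Cxcr4, a chemokine receptor, of 1.06 ± 0.24 (edgeR adjusted p = 0.214).

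No gene passed the edgeR threshold in C3H against B6 averaged over weeks, where 514 had an unadjusted p under 0.05 and DESeq2 called 5. Camera passed 9 lists, with type I interferon genes higher (median 0.28, adjusted p = 5.96e-14), and 0 of them passed with an estimated correlation, where the adjusted p of that list was 0.416. At week 1, 588 genes had an unadjusted p under 0.05 and DESeq2 called 13. Without C3H week 1 replicate 2, the deeper library of its pair, edgeR called 272 genes at week 1 and 52 averaged over weeks.

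Monocyte-like cells labelled C3H and BALB did not differ in any single gene past the edgeR threshold. The neutrophil genes S100a8 and S100a9 had log2 fold changes of -1.91 ± 0.45 and -2.35 ± 0.57 in C3H against BALB (edgeR adjusted p = 0.862 and 0.923). Nonclassical genes were lower in C3H by camera (median -0.12, adjusted p = 0.000725) and ribosomal genes higher (median 0.13, adjusted p = 5.92e-20), with adjusted p of 0.868 and 0.619 with an estimated correlation. At an unadjusted p under 0.05 there were 305 genes, and DESeq2 called 1.

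At week 4 no gene difference of BALB or C3H against B6 passed the edgeR threshold in monocyte-like cells, and C3H against BALB was not tested within a week. Pirb had a log2 fold change of 0.00 in BALB against B6, and Lpl of 0.94 ± 0.29 (edgeR adjusted p = 1). BALB against B6 had 278 genes and C3H against B6 274 genes at an unadjusted p under 0.05, and DESeq2 called 0 in both. On simulated counts this comparison recovered 53% of 2-fold changes for BALB and 48% for C3H, among genes above a minimum mean level.

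The difference between BALB and B6 changed from week 1 to week 4 in 9 genes (edgeR interaction). Lilra5 went from 2.99 to -0.45, with an interaction of -3.43 ± 0.48 (edgeR adjusted p = 0.00400). Lpl went from -1.25 to 0.94, an interaction of 2.19 ± 0.37 (edgeR adjusted p = 0.0199), and Ace from 1.74 to 0.13, an interaction of -1.60 ± 0.31 (edgeR adjusted p = 0.0408) that was 0.35 in classical-like cells alone. The other genes were Cebpb, a transcription factor of myeloid cells, Stap1, Hpgd, Bcl2a1d, Abcg1 and Stip1, of which Cebpb, Stap1 and Bcl2a1d are named after their values were seen. The interaction of Pirb was 0.50 with an edgeR adjusted p of 0.307. For C3H against B6 the interaction passed in 0 genes with edgeR (277 at an unadjusted p under 0.05) and in 0 with DESeq2. The BALB interaction count was 800 at an unadjusted p under 0.05, was 31 with DESeq2, and lay between 0 and 37 as each library was left out, with 0 without BALB week 1 replicate 1. It was 0 without nonclassical-like cells and in all kept cells with edgeR (566 and 796 at an unadjusted p under 0.05), and 1 with a replicate block.

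**Figure D2:**
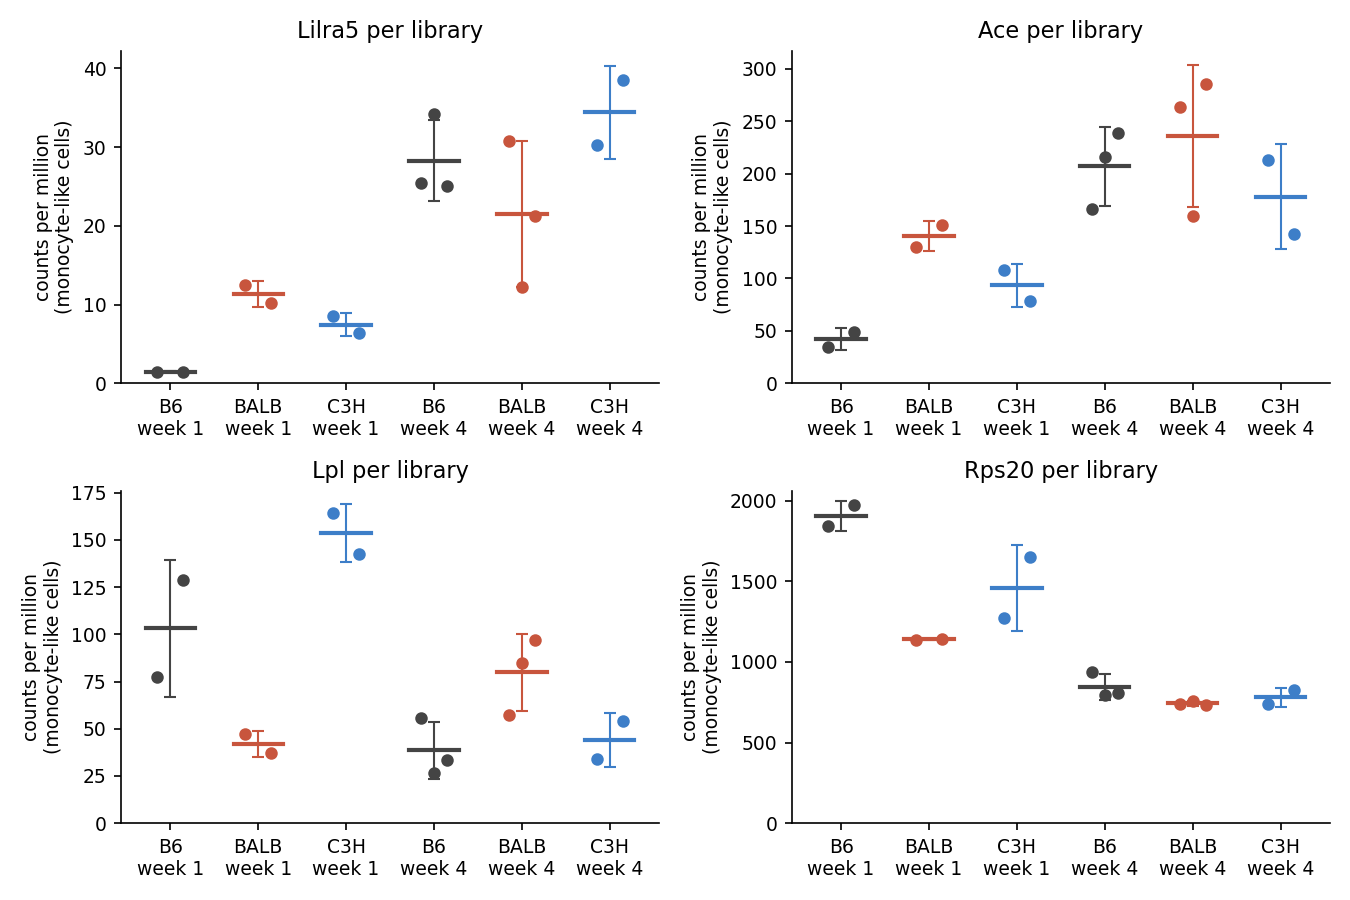
CPM of Lilra5, Ace, Lpl and Rps20 in the summed monocyte-like cells, 1 point per library, with the group mean as a line and the SD as a bar. Lilra5 averaged 1.45 CPM in B6 week 1 and 11.3 CPM in BALB week 1, and Rps20 averaged 1906 and 1139.9 CPM in the same groups.

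The differences of BALB and of C3H from B6, averaged over weeks, were correlated across genes (r = 0.609 over 7594 genes, which are not independent), and 69.9% of genes had the same sign in both. Both differences use the same B6 libraries. Simulated counts with unchanged groups and the same shared B6 libraries gave a mean r of 0.412 and at most 0.438. The covariance was 0.0453 against a simulated mean of 0.0212. With the B6 libraries divided between the comparisons, r was 0.182 and 0.224. No gene could pass in both comparisons, since C3H against B6 called 0 genes, so the overlap of calls says nothing here.

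From week 1 to week 4, averaged over the labels, monocyte-like cells had more nonclassical transcripts and fewer classical ones. Cd300e, an activating receptor of nonclassical monocytes, rose by 2.72 ± 0.19 averaged over labels (edgeR adjusted p = 2.2e-09). In the libraries labelled B6, which had the lowest nonclassical-like share at week 1, it went from 5.11 ± 1.35 CPM (n = 2) to 63.5 ± 8.95 CPM (n = 3). Adgre4 rose by 1.96 ± 0.12, Fabp4 by 1.77 ± 0.13 and Eno3 by 1.81 ± 0.16. Of the 20 nonclassical genes 16 rose and 1 fell, Tgfbi (-0.55 ± 0.09, named after its value was seen), and of the 18 classical genes 0 rose and 11 fell, including Chil3 (-1.30 ± 0.11), S100a4 (-0.94 ± 0.08), Fn1, fibronectin (-1.11 ± 0.11), and Lyz2, lysozyme (-0.56 ± 0.05). Camera gave adjusted p of 5.96e-21 and 1.63e-10 for these lists, and 0.0369 and 0.00942 with an estimated correlation, or 0.07998 and 0.0301 when a replicate block is added. Without nonclassical-like cells, 2 of 16 nonclassical genes rose and 1 fell (median 0.06, camera adjusted p = 0.301), and 3 of 18 classical genes rose and 7 fell (median -0.18, camera adjusted p = 0.0121, and 0.315 with an estimated correlation). Ly6c2, Ccr2 and Cx3cr1 had log2 fold changes of -0.22 ± 0.15, -0.07 ± 0.09 and -0.13 ± 0.11 (edgeR adjusted p = 0.303, 0.591 and 0.415).

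In all 1003 genes rose and 872 fell of 7594 (edgeR, Benjamini-Hochberg), and 248 of these changed by a log2 fold of at least 1. DESeq2 called 1535. The count was 3567 in all kept cells, 1136 without nonclassical-like cells, 720 in classical-like cells alone and 896 after thinning to the smallest library. Week differs together with mitochondrial share and library, so RNA quality or library batch cannot be told apart from time after immunization.

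Of the 4 PIR genes tested 3 fell at week 4, Gm14548 (-1.39 ± 0.16, ENSMUSG00000074417, chromosome 7 from 3884242 to 3898120), Lilra6 (-0.61 ± 0.10) and Pirb (-0.33 ± 0.08, ENSMUSG00000058818, chromosome 7 from 3711409 to 3720391), with a camera adjusted p of 0.00177 and an adjusted p of 0.0516 with an estimated correlation. Pira2 had a log2 fold change of -0.17 ± 0.12 (edgeR adjusted p = 0.320). Of 31 other myeloid receptors 9 rose and 4 fell, with Lilra5 at 2.44 ± 0.21, the Fc receptor Fcgr4 at 1.32 ± 0.12 and Treml4 at 1.32 ± 0.15 (camera adjusted p = 0.0392, and 0.176 with an estimated correlation). Of 23 MHC class I genes 6 rose and 2 fell (camera adjusted p = 0.141), including H2-Q6 (1.88 ± 0.25), Tap2, a peptide transporter (0.52 ± 0.10), and B2m (0.28 ± 0.06), which was lower at week 4 over all kept cells (-0.31 ± 0.08). Of 8 MHC class II genes 3 rose and 2 fell (camera adjusted p = 0.455), with Cd74 at 1.18 ± 0.14 and H2-Aa at 0.59 ± 0.19. Cluster 6, led by MHC class II genes, was left out of these cells, so the values depend on that choice. With both unnamed clusters added H2-Aa was at -0.27 ± 0.28. In nonclassical-like cells alone Cd74 was at -0.08 ± 0.09 and H2-Aa at -0.59 ± 0.14.

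Of 53 type I interferon genes 14 rose and 1 fell, including Ifi44 (1.93 ± 0.26), the RNA sensor Ifih1 (0.87 ± 0.11) and Trim30a (0.47 ± 0.08), with a camera adjusted p of 0.000495 and an adjusted p of 0.636 with an estimated correlation. Of 12 interferon-gamma-induced genes 3 rose and 0 fell (camera adjusted p = 0.148), among them Cd274, the ligand PD-L1 (3.32 ± 0.42), and Gbp2 (0.44 ± 0.12). Of 22 NF-kB and cytokine genes 7 rose and 0 fell, among them Rel (0.80 ± 0.09), Nfkbiz (0.90 ± 0.12) and Nfkbia (0.44 ± 0.09), with a camera adjusted p of 0.0245 and an adjusted p of 0.232 with an estimated correlation. Of 24 immediate early and dissociation stress genes 11 rose and 2 fell, with Jund at 1.36 ± 0.09, Dusp1 at 1.83 ± 0.25 and Nr4a1, a factor of nonclassical monocytes, at 0.60 ± 0.09 (camera adjusted p = 0.000228, and 0.405 with an estimated correlation). Of 14 costimulation genes 6 rose and 0 fell, among them Cd83 (1.71 ± 0.31) and Cd274 (camera adjusted p = 0.01004, and 0.213 with an estimated correlation).

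Of 14 phagocytosis and complement genes 5 rose and 2 fell, with the scavenger receptor Cd36 at 2.10 ± 0.20, Axl at 1.11 ± 0.16 and Itgax at 1.63 ± 0.27 (camera adjusted p = 0.0404, and 0.213 with an estimated correlation). Of 18 migration genes 7 rose and 4 fell (camera adjusted p = 0.114), with the integrin chain Itgb1 at 0.96 ± 0.10 and the chemokine Ccl9 at -0.52 ± 0.08. Of 18 cholesterol genes 4 rose and 0 fell (camera adjusted p = 0.114), including Abcg1 (0.86 ± 0.13) and Hmgcs1 (0.84 ± 0.16). Of 27 chromatin-modifying genes 6 rose and 2 fell (camera adjusted p = 0.284), with Kmt2d at 0.95 ± 0.21, Tet2 at 0.59 ± 0.14 and Dnmt3a at 0.94 ± 0.22. Of 18 glycolysis genes 3 rose and 7 fell, including Gapdh (-0.75 ± 0.07), Gpi1 (-0.47 ± 0.07) and Hk2 (-0.59 ± 0.11), with a camera adjusted p of 0.0568. Of 45 oxidative phosphorylation genes 0 rose and 15 fell, including Atp5g3 (-0.57 ± 0.09) and Cox7b (-0.35 ± 0.07), with a camera adjusted p of 1.67e-05 and an adjusted p of 0.342 with an estimated correlation. Of 11 cell cycle genes 3 rose and 3 fell (camera adjusted p = 0.743), among them Mcm4 (0.84 ± 0.23) and Pcna (-0.46 ± 0.12). Cluster 3, led by cycling and haemoglobin genes, was left out of these cells. H2afz, also of this list, was at -0.34, and at 0.014 with both unnamed clusters added.

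Of 78 cytosolic ribosomal protein genes 67 fell and 1 rose, with Rps20 at -0.90 ± 0.07, Rps12 at -0.90 ± 0.07 and Rpl31 at -0.74 ± 0.07 (camera adjusted p = 9.8e-46, and 0.0516 with an estimated correlation). Among the genes with the lowest log2 fold changes were the ribosomal pseudogenes Rpl7a-ps5 (-2.96 ± 0.50), Rpl13a-ps1 (-2.50 ± 0.42) and Rpl10-ps3 (-2.46 ± 0.15). All 7 ribosomal pseudogenes tested fell, with a median of -1.78 against -0.59 for their 7 parent genes, whose reads they may share. The reads were not examined, and the cause of the larger fall was not tested. Of 12 mitochondrially encoded genes 5 rose and 4 fell, with mt-Cytb at 0.43 ± 0.07 and mt-Atp8 at -2.13 ± 0.39 (camera adjusted p = 0.989). Other genes that fell were Nme2 (-2.22 ± 0.35), Klhl21 (-2.19 ± 0.25), Wdr89 (-2.18 ± 0.14), Trim25 (-2.18 ± 0.15), Gm10269 (-2.35 ± 0.31) and Itgb3 (-2.10 ± 0.39). Others that rose were G0s2 (2.18 ± 0.21), the tetraspanin Cd9 (2.13 ± 0.23), Dusp16 (2.12 ± 0.22), Slc12a2 (2.09 ± 0.25), Lpcat4 (2.02 ± 0.30) and Bcl2a1b (1.97 ± 0.16).

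Transcripts of other cell types moved in both directions between the weeks. All 4 red cell genes tested rose, with Hbb-bs, a beta globin with near-identical copies, at 2.40 ± 0.27 and Hba-a1 at 2.39 ± 0.28 (camera adjusted p = 3.6e-06, and 0.1004 with an estimated correlation). Cluster 3, led in part by these haemoglobin genes, was left out of the cells tested. Of 6 neutrophil genes 0 rose and 4 fell, with S100a9 at -2.01 ± 0.41 and Cd177 at -0.56 ± 0.08 (camera adjusted p = 0.00567, and 0.0683 with an estimated correlation). S100a8 fell (-1.11 ± 0.35) but rose in cells with at least 1000 genes (1.49 ± 0.31). Of 2 B cell genes 0 changed (camera adjusted p = 0.651), of 3 T and NK cell genes 1 rose, Klrk1 (0.95 ± 0.20, camera adjusted p = 0.520), and of 8 dendritic cell genes 1 rose and 1 fell (camera adjusted p = 0.591). Of 5 red pulp macrophage genes 1 rose, Axl, and 2 fell, Trf (-0.57 ± 0.10) and Adgre1 (-0.31 ± 0.09, but 0.19 in nonclassical-like cells alone), with a camera adjusted p of 0.971. Of the basophil, mast cell and eosinophil genes Prss34 alone was tested, with a log2 fold change of 3.65 ± 1.25 (edgeR adjusted p = 0.0383).

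**Figure D3:**
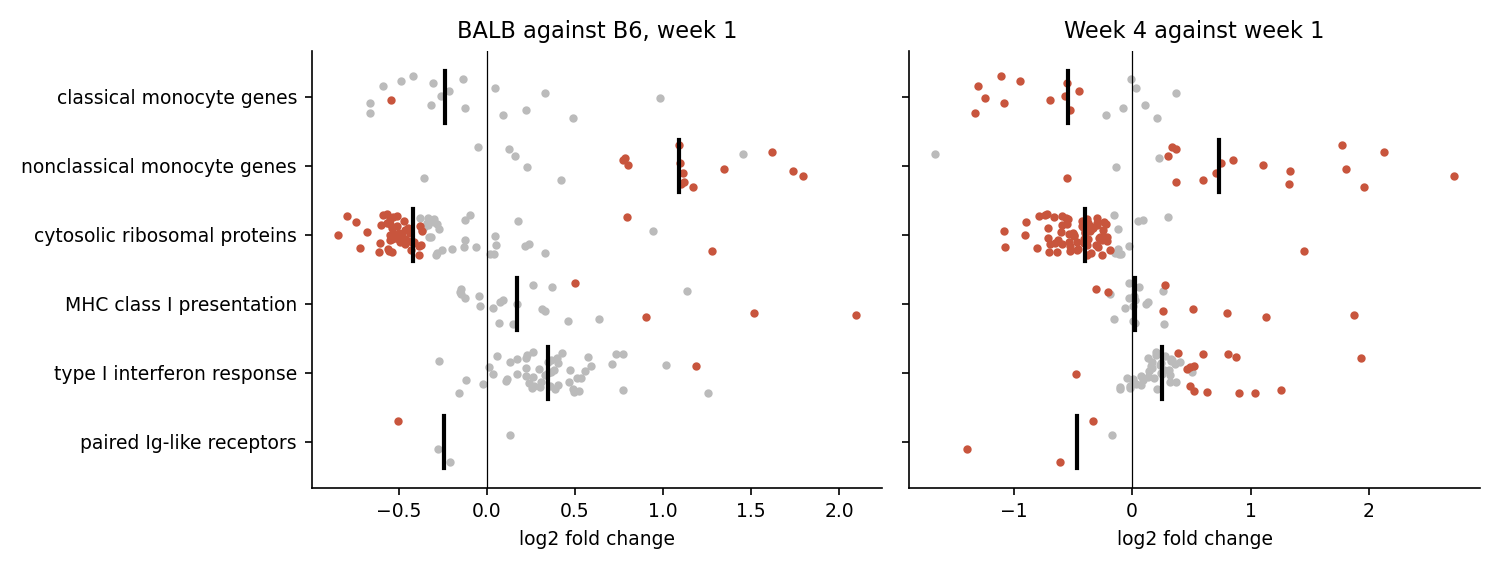
Log2 fold change of each tested member of 6 gene lists, 1 point per gene, for BALB against B6 at week 1 (left) and week 4 against week 1 averaged over labels (right), with genes past the edgeR threshold in red and the list median as a line. The nonclassical list had medians of 1.09 and 0.73, and the ribosomal list had medians of -0.42 and -0.40.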

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

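The interaction comparison was planned, and the tests of explanations below were chosen after the results were seen.

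In 9 genes the difference between the libraries labelled BALB and B6 changed from week 1 to week 4 past the edgeR threshold, tested as an interaction. The myeloid receptor gene Lilra5 went from 2.99 to -0.45, an interaction of -3.4350 on the log2 scale (edgeR adjusted p = 0.00400), and Lpl, lipoprotein lipase, from -1.25 to 0.94, an interaction of 2.1921 (edgeR adjusted p = 0.0199). The transcription factor gene Cebpb went from 0.84 to -0.28 (-1.1205, edgeR adjusted p = 0.0199), Stap1 from 0.89 to -0.23 (-1.1243), Hpgd from 1.19 to -0.44 (-1.6300), Ace from 1.74 to 0.13 (-1.6046), Abcg1 from 1.21 to -0.33 (-1.5342) and Stip1 from 0.87 to -0.79 (-1.6597), with an edgeR adjusted p of 0.0408 each. Bcl2a1d, whose reads may be shared with near-identical copies, went from 1.72 to 0.22 (-1.4950, edgeR adjusted p = 0.0483). In classical-like cells alone Ace had an interaction of 0.35. The count of genes was 0 without nonclassical-like cells and in all kept cells, and 1 with a replicate block. The Lilra5 interaction lay between -3.89 and -1.85 in the 29 alternatives that tested it and was past the threshold in 23, and that of Abcg1 between -1.88 and -0.51 in 32, past it in 10. The count was 0 without BALB week 1 replicate 1, 1 without B6 week 4 replicate 2 or 3 or BALB week 4 replicate 2, 3 without B6 week 1 replicate 1, 15 without B6 week 1 replicate 2 or BALB week 4 replicate 3, and 37 and 36 without C3H week 1 replicate 1 and 2.

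In the gene differences between the libraries labelled BALB and B6 at week 1, a larger share of nonclassical-like cells in BALB as the whole cause is argued against, since without these cells the log2 fold change of a called gene was at a median of 0.965 of its value with them (quartiles 0.850 and 1.02), over the 279 of 303 called genes tested without them. For the 10 of 13 called genes of the nonclassical list that were tested, such as Ace and Adgre4, the ratio was 0.459 (quartiles 0.239 and 0.518), so their rise and the share of nonclassical-like cells cannot be told apart, because the same genes define the cells. A single B6 library that stands apart stays open: 195 of the 197 genes called with replicate 1 alone had a median ratio of 0.629 when measured with replicate 2 (quartiles 0.452 and 0.879), the 60 genes called with replicate 2 alone had 0.841 with replicate 1, and the count fell from 303 to 60 without replicate 1. A first form of this test, on genes called with both libraries, had argued against it and was dropped because such genes favour agreement. A difference that the labels name stays open and was not tested apart from differences between single libraries.

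In the gene differences between week 4 and week 1, a larger share of nonclassical-like cells as the whole cause is argued against. Without these cells the median ratio was 0.9295 over the 1760 of 1875 called genes tested (quartiles 0.689 and 1.10). Here too only cluster 8 was removed, and the makeup of the other clusters was not tested. After thinning of the sums to the smallest library the median ratio was 1.0027 over the 1548 of 1875 tested (quartiles 0.841 and 1.17). Random thinning keeps the expected fold change, so this ratio does not test a lower total count or count per cell at week 4. Both stay open. RNA quality or library batch cannot be told apart from time after immunization, since every week 4 library had a median mitochondrial share of 5.28% or more. Tissue stays open too, since the sample descriptions name lymph node at week 1 and tumor at week 4. C3H week 1 replicate 1, the low-quality library, differed from replicate 2 by a median of 0.0942 of the week difference over 1875 genes (quartiles -0.376 and 0.531). This is a single pair of libraries, compared after the low-quality clusters were removed. The median count per monocyte-like cell was 5314 in replicate 1 and 5746.5 in replicate 2, against 2327 to 3267 at week 4. The pair therefore does not test low RNA quality. Time after immunization stays open and untested.

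For BALB against B6 averaged over weeks, 15 of 60 splits gave as many genes as the real 8, with up to 107 in another split, so chance is not excluded, and the higher counts may reflect a structure of the libraries other than the labels, which was not tested. For C3H against B6 and C3H against BALB the real counts were 0 with edgeR (514 and 305 genes at an unadjusted p under 0.05, and 5 and 1 with DESeq2), so all 60 of 60 splits had to give as many and say nothing about chance, with up to 3 and 13 genes. For week 4 against week 1, 1 of 100 splits drawn from 600 possible, the real one, gave 1875 genes and the highest other 883. A random division of the libraries is argued against, but not a batch that follows the weeks. Chance between mice is not tested, since the libraries of a group may not be separate mice. For BALB against B6 at week 4, the 10 splits are too few, with 0 genes (edgeR, 278 at an unadjusted p under 0.05 and 0 with DESeq2) in the real split and at most 0 in the others.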

How the results depend on the processing

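Sums without nonclassical-like cells, with low-quality clusters added, with both unnamed clusters added and with both kinds added to the shares were chosen after the data had been seen, and the other alternatives were chosen before. Where a value below changed, the cause was not tested, unless the alternative has fewer genes, cells or libraries by its construction.

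The count for week 4 against week 1 was 1875, and lay between 1417 and 1993 as each library was left out. It was 1535 with DESeq2, 248 at a log2 fold change of at least 1, 3567 in all kept cells, 3027 with low-quality clusters added, 1136 without nonclassical-like cells, 896 after thinning, 720 in classical-like cells and 607 in nonclassical-like cells.

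The count for BALB against B6 at week 1 was 303. It was 542 with no low-count filter, 193 with a replicate block, 175 without nonclassical-like cells, 145 with low-quality clusters added, 140 in classical-like cells, 91 at a log2 fold change of at least 1, 86 in nonclassical-like cells, 69 after thinning and 61 in all kept cells. With each library left out it lay between 60 (without B6 week 1 replicate 1) and 514 (without C3H week 1 replicate 2). It was 88 without BALB week 1 replicate 2, 103 without BALB week 1 replicate 1, 197 without B6 week 1 replicate 2 and 513 without C3H week 1 replicate 1.

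The count for BALB against B6 averaged over weeks was 8. It was 195 with no low-count filter, 91 with DESeq2, 83 with only the groups compared, 19 in cells with at least 1000 genes, 15 at Leiden resolution 2.0, 13 at Leiden resolution 0.5, 13 in nonclassical-like cells, 12 with both unnamed clusters added, 5 with low-quality clusters added, 4 in all kept cells, 1 at a log2 fold change of at least 1, and 0 in classical-like cells or without nonclassical-like cells. With each library left out it lay between 0 (without BALB week 4 replicate 1 or 3) and 115 (without C3H week 1 replicate 1 or 2). It was 16 without B6 week 1 replicate 2, 3 without B6 week 4 replicate 2 or either C3H week 4 library, 2 without BALB week 1 replicate 1, and 1 without BALB week 1 replicate 2 or B6 week 4 replicate 1.

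The interaction count of BALB and week was 9. It was 134 with no low-count filter, 33 with only the groups compared, 31 with DESeq2, 5 with doublets kept, 4 after thinning, 3 with both unnamed clusters added, 2 in cells with at least 1000 genes, 1 in cells with at least 200 genes, in classical-like cells, in nonclassical-like cells and with a replicate block, and 0 in all kept cells and without nonclassical-like cells. With each library left out it lay between 0 (without BALB week 1 replicate 1) and 37 (without C3H week 1 replicate 1).

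The count for C3H against B6 averaged over weeks was 0 with edgeR (514 at an unadjusted p under 0.05, 5 with DESeq2). It was 46 with no low-count filter, 7 in all kept cells, 6 at Leiden resolution 2.0, 4 at Leiden resolution 0.5 and with doublets kept, 2 in cells with at least 200 genes, in nonclassical-like cells, after thinning and with both unnamed clusters added, and 1 with only the groups compared. It lay between 0 and 52 (without C3H week 1 replicate 2), and was 1 without BALB week 4 replicate 1. At week 1 the count was 1 with edgeR and 13 with DESeq2, 148 with no low-count filter, 2 in nonclassical-like cells, and 0 in cells with at least 200 genes or at least 1000 genes, with doublets kept, at both Leiden resolutions, in all kept cells, in classical-like cells, with a replicate block, with only the groups compared, after thinning, without nonclassical-like cells and with both unnamed clusters added. It lay between 0 and 272 (without C3H week 1 replicate 2), and was 13 without B6 week 1 replicate 2 and 0 without B6 week 1 replicate 1, C3H week 1 replicate 1 or any B6 week 4 library.

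At week 4 BALB against B6 had 0 genes with edgeR (278 at an unadjusted p under 0.05, 0 with DESeq2) and 3 with no low-count filter. C3H against B6 had 0 with edgeR (274 at an unadjusted p under 0.05, 0 with DESeq2), 6 with no low-count filter, 2 in cells with at least 200 genes, with doublets kept and at Leiden resolution 0.5, and 1 at Leiden resolution 2.0, with only the groups compared and with both unnamed clusters added. Both stayed at 0 as each library was left out. C3H against BALB had 0 with edgeR (305 at an unadjusted p under 0.05), 7 with no low-count filter, and 1 with DESeq2, after thinning and without nonclassical-like cells, and lay between 0 and 1 as each library was left out. The interaction count of C3H and week was 0 with edgeR (277 at an unadjusted p under 0.05, 0 with DESeq2), 10 with no low-count filter, and between 0 and 4 as each library was left out.

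The nonclassical share for C3H against B6 was 8.71 points higher in cells with at least 200 genes (exact permutation adjusted p = 0.0444). With a replicate block the week differences in shares were 34.1 and -38.3 points (exact permutation p = 0.03125, the smallest this block allows, adjusted p = 0.125 each). No adjusted p under 0.05 was possible there, so the block does not test these calls, and the replicate numbers do not pair the libraries. The week difference in the nonclassical share, 35.8 points, was 25.9 in cells with at least 1000 genes, 20.8 at Leiden resolution 2.0, 19.4 with both unnamed clusters added, 17.7 at Leiden resolution 0.5, 17.2 with doublets kept and 10.1 in cells with at least 200 genes, and it stayed past the threshold in these. With unnamed and low-quality clusters added it was 6.68 points and not past it (exact permutation p = 0.015, adjusted p = 0.06). The cells added there entered the total only and could not count as nonclassical-like. The week difference in the monocyte-like share, -39.6 points, was -16.5 with unnamed and low-quality clusters added and between -45.5 and -31.4 points under the other cell definitions. As each library was left out, the week difference in the nonclassical share lay between 34.02 and 37.5 points, and that in the monocyte-like share between -43.6 and -35.5 points. The difference in the monocyte-like share was 1.996 points without C3H week 1 replicate 1 and -10.2 without C3H week 1 replicate 2 for C3H against B6, and 5.02 and -7.18 for C3H against BALB.

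Of the gene lists, 13 passed camera for BALB against B6, 9 for C3H against B6, 4 for C3H against BALB and 13 for week 4 against week 1. With an estimated correlation 0, 0, 0 and 2 passed, with fry 1, 0, 0 and 14, and with a replicate block 12, 10, 3 and 15. With the B6 libraries split between them, the correlation of the BALB and C3H differences was 0.18 and 0.22.

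Several named genes turned in direction between week 4 and week 1. In cells with at least 1000 genes H2afz was at 0.031, S100a8 at 1.49 and Lcn2 at 0.42. At Leiden resolution 2.0 H2afz was at 0.00032 and S100a8 at 0.73, and with doublets kept H2-Aa was at -0.26. In all kept cells B2m was at -0.31 and Itgal at -0.011. In classical-like cells Ccr2 was at 0.34, H2-Q7 at -0.079, H2-DMa at 0.0032, H2-Aa at -0.49, Itgal at -0.17, Kdm6b at -0.35 and Dpp4 at -0.067. In nonclassical-like cells Cd74 was at -0.080, H2-Aa at -0.59, Ifit2 at -0.053, Jak2 at -0.058, Itgal at -0.024 and Adgre1 at 0.19. Without nonclassical-like cells Ccr2 was at 0.34 and Itgal at -0.17, with low-quality clusters added B2m was at -0.10 and Naaa at 0.055, and with both unnamed clusters added H2-Aa was at -0.27, H2afz at 0.014 and S100a8 at 0.76. For BALB against B6 at week 1, Hes1 was at -0.071 in classical-like cells, and after thinning Lpcat4 was at -0.090 and Dpp4 at -0.54. The interaction of Ace was 0.35 in classical-like cells. The cause was not tested.

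Of 168 calls of named genes, 168 held with the size factors of DESeq2 in edgeR, 164 with no low-count filter, 144 with a replicate block and 97 in all kept cells. DESeq2 kept 143 of 151, thinning 101 of 143 (2 turned), sums without nonclassical-like cells 94 of 148 (1 turned), nonclassical-like cells 70 of 144 (6 turned) and classical-like cells 57 of 125 (8 turned). With the depth and number of the week 4 libraries, simulated 2-fold changes were recovered at 53% for BALB and 48% for C3H, and 4-fold changes at 94% and 89%. These hold for genes above a minimum mean level.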

Other observations

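The values of other cell classes by week follow without a test, and the tests of explanations and the interactions of shares in this part were chosen after the results were seen. Basophil or mast cell-like cells, led by Prss34 and Mcpt8, were 10 of 11608 kept cells at week 1, of which 9 were in BALB week 1 replicate 1, and 280 of 7261 at week 4, with 1.26% to 5.89% per library. Migratory dendritic cell-like cells were 29 of the kept cells at week 1 (0% to 0.492% per library) and 119 at week 4 (1.10% to 2.85%). Low-quality cells with dendritic cell genes were 76 (0.499% to 1.54%) and 731 (7.42% to 14.5%). The ranges of the weeks overlapped for progenitor-like cells, 139 (0.629% to 1.93%) and 184 (0.589% to 4.54%), and for cDC2-like cells, 711 (1.74% to 7.05%) and 406 (3.35% to 8.57%). The difference between C3H and B6 in the monocyte-like share of kept cells was -15.9 points at week 1 and 7.65 points at week 4, an interaction of 23.5 points (exact permutation p = 0.0167, the smallest this design allows, adjusted p = 0.0667). The week 4 difference was below 0 under 5 of 7 other cell definitions (-6.88 to 5.71 points over all 7), and that of week 1 lay between -16.3 and 0.613 points, so opposite directions by week are not shown. The interaction was between 8.84 and 14.5 points under 6 other cell definitions (exact permutation p = 0.1 to 0.767), 0.992 points with unnamed and low-quality clusters added (p = 0.967), 11.3 points without C3H week 1 replicate 1 and 35.7 points without C3H week 1 replicate 2. For BALB this interaction was 12.4 points (exact permutation p = 0.1, adjusted p = 0.167) and lay between -3.17 and 15.8 points under other cell definitions, and the interaction of the nonclassical share was -9.91 points for C3H (exact permutation p = 0.167, adjusted p = 0.167), and between -3.66 and 8.51 points under other cell definitions. The logit difference, which the test uses, was -0.999 for the latter and stayed below 0 in all 7 of these, between -0.612 and -0.0695, and for the monocyte-like share of BALB it was 0.592 and lay between -0.0475 and 0.907.

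Il2rg, the common gamma chain of several cytokine receptors, was near absent in all 14 libraries, with at most 1.67 CPM, while Il10rb, Csf2rb and Ifngr1, chosen after the values were seen, reached at least 71.3, 54.1 and 511 CPM in every library. Too few counts to detect Il2rg is argued against, since a count of 3 corresponds to at most 2.55 CPM in any library. A candidate explanation is that all libraries come from mice that lack Il2rg. It also holds that the labels name something other than the mouse strain, such as the cells used to immunize. The titles, which name B6, BALB and C3H mice, go against that reading of the labels. Mice of the labelled strains stay open, since 0 genes were on in every library of one label and off in every library of another, while H2-Ea is not in the files and no library of known strain is at hand. The Il2rg level in monocytes with an intact gene is not in these data, so the Il2rg part of the hypothesis rests on the low value. The part about the labels rests on the 0 genes on in one label and off in another. The 0 counts of Cd3e, Igkc, Ncr1 and Gzma do not test it, since the libraries are of sorted cells. Reads over the exons of Il2rg or strain variants, which would test the hypothesis, are not in the deposited counts.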
